A study of Mus musculus with 10 samples.

How the data were processed

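RNA abundance was measured with 1-colour Affymetrix 3′ expression arrays in 10 B16 tumors on the C57BL/6 background, 5 of wild-type genotype and 5 labelled Bach2-deficient. Per the labels' protocols, whole tumors were dissected and mechanically dissociated to single-cell suspensions, total RNA was extracted with Trizol, and biotinylated cRNA was hybridised. The values therefore mix RNA of the melanoma cells with RNA of all other cells in the tumor. The deposited table holds log2 expression values made by the authors, and per the submitters' processing notes the tools were RMA (robust multi-array average, which corrects background, normalizes quantiles between arrays and summarises probes) and Partek; their versions are not given in the sources used here. The log2 scale was read from the deposited values, which ran from 1.99 to 14.4 with a median close to 5.8 on each array. The values were used as deposited, with no new background correction or normalization. No detection calls were used, so a dim probe set carries no statement of presence or absence and the size of a change from or to a mean under 4.98 (the level that bounds the dimmest 30% of genes) is not exact, and the number of arrays limits the precision.

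Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether the 5 tumors of a group came from separate animals, so p-values measure the spread between these samples, which may in part be technical. The labels give no sex, age, hybridisation date or batch. They do not say which part of Bach2 was deleted, nor whether the deficiency lay in the host, the tumor cells or both.

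The table held 45101 probe sets, of which 64 were control probe sets. The platform annotation gave 1 gene symbol for 34945 probe sets, several symbols for 932 and none for 9160. Only the first kind was named and used in the comparisons, and those without a symbol were tested on their own. Of the single-gene probe sets, 34741 had a gene ID in the RefSeq gene table used (assembly GRCm38.p6), and 0 symbols changed on the update. Each gene was represented by its probe set with the highest mean log2 value over all 10 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. Probe sets of 90 genes were called in opposite directions when each was tested by itself. No coordinates are given, because the files name no genome build; the gene table served for names and for the order of neighbouring genes.

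Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, without an intensity trend or robust moderation), over all 10 arrays with genotype as the single factor. Changes are log2 values of Bach2-deficient minus wild type, with the standard error (SE) of the fit, and adjusted p-values are Benjamini-Hochberg values over the 18193 genes. A gene is said to have risen or fallen at an adjusted p under 0.05. Fold values are 2 to the power of the log2 change; background signal in RMA values of dim genes tends to shrink such folds. Data were simulated with the spread of the 18193 genes of this comparison and 200 changed genes, each gene drawn independently. The fit called 67% of genes changed by 1 on the log2 scale and 93% of those changed by 2. Unchanged genes made up 8.05% of its calls. Measured genes vary together, and 5226 of them were called, far more than the 200 simulated as changed. These shares need not hold for them.

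Lists of genes (27) were fixed before the data were examined, covering T, NK, regulatory and B cells, myeloid and dendritic cells, interferon and cytokine programmes, melanocyte, stromal, skin, muscle, fat and blood cells, cell cycle, hypoxia, stress and sex-linked genes. Of these, 26 were tested with limma's fry (directional p, Benjamini-Hochberg over the 26 lists), and the sex-linked list was only described. fry asks whether the genes of a list move one way on balance, not whether they move more than other genes. Counts of members called over all genes are given with the counts adjusted over the list alone. camera with a correlation preset at 0.01 called 20 lists, and camera with the correlation estimated for each list called 0, so the adjusted p of the latter stands beside each list. On simulated unchanged lists, whose genes were drawn independently, 3 of 100 had a fry p under 0.05. Genes of many measured lists are correlated (estimated at 0.57 for the T cell list), so this does not give the rate for them. Some listed genes had no probe set of their own symbol here and are not analysed here. Gzma stood on both the cytotoxic and NK lists, and Ctla4 and Entpd1 on both the regulatory and inhibitory receptor lists. For every tested list the median, the mean and the test had the same sign.

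Named genes followed a rule also fixed before the data were examined. It took Bach2, Foxp3, Ifng, Cd4 and Cd8a in any case, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, and for each list the 2 called members with the smallest p. This gave 69 genes. Members named beyond these were chosen after their values were seen. Probe sets whose names end in _x_at or _s_at can bind related transcripts; 9 named genes rest on such probe sets. Of the 34 named genes with several probe sets, all probe sets pointed the same way for 31.

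Single values per array (control probe sets, 3′ minus 5′ log2 values of Actb and Gapdh, sex-linked genes, differences between genes) were compared with 2-sided exact permutation tests over all 252 splits of the arrays, whose smallest p is 0.00794, and Benjamini-Hochberg values were taken over the 15 control, quality and sex-linked quantities. The alternatives were a filter on the dimmest 30% of genes, the mean of a gene's probe sets, median centring, a repeated quantile normalization, trended robust moderation, array weights, the replicate number as a block, the melanocyte list mean as a covariate, every probe set tested by itself, a minimum change of 1 on the log2 scale, other list tests, and leaving out each array in turn. A term that marks each array as Xist-high or Xist-low (cut at a log2 level of 9) was added after the data were seen, as a marker of host sex. Figures were drawn with matplotlib 3.10.9.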

Results

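RNA was profiled on expression arrays in 10 tumors of B16, a transplantable melanoma line of C57BL/6 origin. Wild-type tumors (5) were compared with tumors labelled Bach2-deficient (5). Bach2 encodes a transcriptional repressor expressed in lymphocytes. The comparison asks how the RNA content of a whole tumor, including its infiltrating immune cells, differs between these labelled groups. All 10 arrays had a median log2 value between 5.80 and 5.88, and the number of arrays limits the precision.

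Bach2 itself was read by 3 probe sets, and all 3 were lower in the Bach2-deficient tumors. Probe set 1436515_at read 4.70 ± 0.55 against 5.75 ± 0.54 in wild type (log2, mean ± SD, n = 5 each), a fall of 1.05 with a limma adjusted p of 0.033 over all probe sets. Probe set 1445460_at, the brightest and the one that stands for the gene, read 5.89 ± 0.55 against 6.96 ± 0.76. Its change of -1.07 (SE 0.38) had an adjusted p of 0.0551 over the 18193 genes. The gene passed with the dim-gene filter (-1.07, adjusted p = 0.0428), as the mean of its probe sets (-0.82, adjusted p = 0.0240) and after repeated quantile normalization (-1.14, adjusted p = 0.0496). It did not pass with median centring, trended robust moderation, array weights, the replicate block, the melanocyte covariate or the Xist term. With 1 array left out it passed only without wild-type replicate 2, and its limma adjusted p reached 0.115. Probe set 1437667_a_at differed by -0.35 with an adjusted p of 0.371. The labels do not state which part of the gene was deleted, and a probe set outside that part checks nothing. The call of 1436515_at was lost in 6 of the 10 fits that left out 1 array, with changes from -1.24 to -0.84, and 1445460_at passed without wild-type replicate 2 (-1.33, limma adjusted p = 0.0223).

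The arrays separated by genotype. Of 18193 genes, 2962 rose and 2264 fell in the Bach2-deficient tumors, 5226 in all or 28.7%. A change of at least 1 on the log2 scale was passed by 1469 genes that rose and 670 that fell. The groups did not overlap for 3436 genes (18.9%), where chance gives 0.794%. The first principal component held 59.7% of the variance and divided the genotypes. Among the largest rises, Gzmd, a granzyme, rose by 6.19 (SE 0.56; an _x_at probe set), and Ifng, which encodes interferon-γ, rose by 5.84 (SE 0.60, limma adjusted p = 0.000245). Gbp2b, a guanylate-binding GTPase, rose by 5.68, the T cell chemokine gene Cxcl9 by 5.33, Ly6i by 5.29, the granzyme genes Gzmb and Gzmg by 5.25 and 5.21, and the lipoxygenase gene Alox15 by 5.18. The wild-type means of Gzmd (3.66), Gbp2b (3.26), Alox15 (4.24), Ly6i (4.74), Ifng (4.95) and Gzmg (4.95) lay under 4.98, the level that bounds the dimmest 30% of genes. With no detection calls such a baseline is not shown to be above background, so no fold is given and the size and order of these changes are not exact. The largest falls included the red cell genes Slc4a1 (band 3 anion exchanger; -5.13, 35.1-fold, an _x_at probe set), Alas2 (-4.16) and Epb42 (-3.47). They also included Apol11b (-3.67), Rapgef3 (-2.89), Sfi1 (-2.73), the matrix gene Mgp (-2.67) and Tpm2, a tropomyosin (-2.66). The Bach2-deficient mean of Epb42 (3.39) lay under 4.98 too, so the size and place of its fall are not exact either. Within wild type the red cell genes varied widely, Slc4a1 from 9.57 to 12.8, Alas2 from 10.3 to 12.7 and Epb42 from 4.90 to 9.51.

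Other features of the samples moved with genotype. The poly-A spike controls, bacterial transcripts added to the RNA before labelling, read 10.1 ± 0.102 on the Bach2-deficient arrays and 12.2 ± 0.180 on the wild-type arrays (log2, SD, n = 5 each), with no overlap (exact permutation p = 0.00794, the smallest this test allows; adjusted p = 0.017). The hybridization controls differed by -0.58 (exact p = 0.00794). The labels give no batch, and why the controls differ was not tested; a technical difference behind them cannot be told apart from genotype. Xist, transcribed from the inactive X chromosome of females, was high on all 5 wild-type arrays (11.4 to 12.2). It was low on 4 Bach2-deficient arrays (4.76 to 6.61), which carried high Eif2s3y, a Y-linked gene (10.5 to 10.9), and high on the remaining one, replicate 2 (11.9, with Eif2s3y at 4.50). With a term for high or low Xist in the fit, chosen after the data were seen, 1030 genes rose and 387 fell. With the melanocyte list mean as a covariate, which itself differed between the groups, 64 rose and 34 fell. Calls of 14 of the 69 named genes were lost with the Xist term and those of 50 with the covariate. A call lost with the covariate need not mean a much smaller change. With it Slc4a1 changed by -4.931, a little less than in the main fit (-5.13). Fabp4 changed by -1.035, more than in the main fit (-0.82). Other changes shrank further, such as Siglecf to 2.043 (3.83 in the main fit) and Ighm to 0.4881 (2.00 in the main fit). These are examples of both kinds. Falls numbered 1388 without Bach2-deficient replicate 2 and 1447 without replicate 4.

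**Figure D1:**
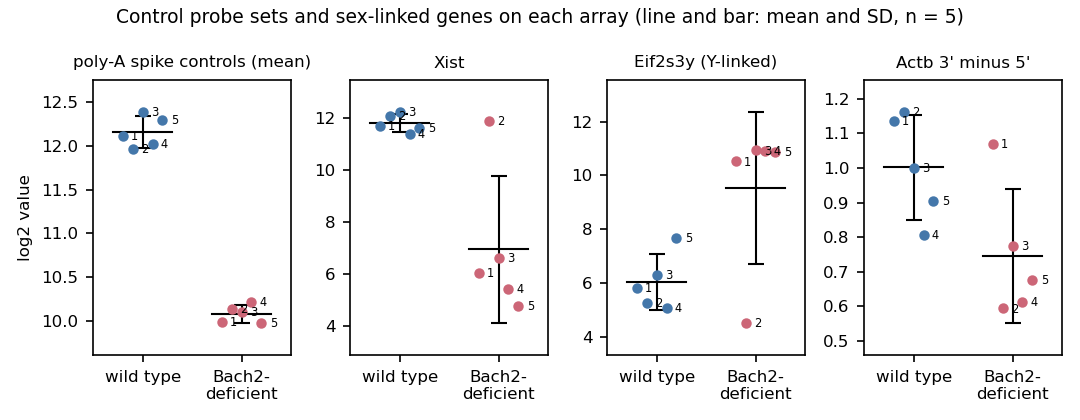
Log2 values on each array for the mean of the poly-A spike controls, Xist, the Y-linked gene Eif2s3y, and the 3′ minus 5′ difference of Actb control probe sets, by genotype; points are arrays numbered by replicate, lines and bars are mean and SD (n = 5), and axes do not start at 0. The poly-A controls separate the genotypes without overlap, and Bach2-deficient replicate 2 lies with the wild-type arrays for Xist and Eif2s3y.

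T cell genes rose together. All 19 measured members of the T cell list rose, with a median change of 2.71 (fry adjusted p = 0.000115; adjusted p = 0.128 with an estimated correlation). Cd8b1 and Cd8a, the chains of the CD8 co-receptor, rose by 4.71 and 4.23 (SE 0.45; 18.7-fold for Cd8a), and Themis, a regulator of T cell receptor signalling, by 4.38. Cd4 rose by 1.69 (3.23-fold, SE 0.26, limma adjusted p = 0.00128). The per-array difference Cd4 minus Cd8a differed by -2.53, Bach2-deficient minus wild type (exact permutation p = 0.00794), so the measured rise of Cd4 was smaller than that of Cd8a. Probe sets differ in affinity and background, so the sizes of these rises cannot be matched. All 24 cytotoxic effector genes rose, with a median of 3.98 (adjusted p = 0.000108; adjusted p = 0.128 with an estimated correlation). Fasl, the ligand of the death receptor Fas, rose by 4.75 and the activating receptor gene Klrk1 by 3.73. The smallest change on that list was that of Prf1, perforin, at 0.37 (adjusted p = 0.0472). Of 11 NK cell genes, 9 rose, with a median of 2.95 (adjusted p = 0.000168; adjusted p = 0.128 with an estimated correlation). Klra8, a Ly49 receptor gene, rose by 3.51 (an _x_at probe set) and the kinase gene Txk by 2.94; Il12rb2 (0.66) and Klra1 (0.08) did not pass. The wild-type means of Cd8b1 (4.77), Fasl (4.52) and Txk (4.02) lay under 4.98, so the sizes of these changes are not exact. Adjusted over the list alone, all 19, all 24 and 10 members passed. These rises came on arrays that also differed in the poly-A controls by -2.07 and in the melanocyte list by -0.59. With the melanocyte list mean as a covariate, the T cell list had a median of 2.03 and 2 of its 19 members passed, with 6 cytotoxic and 1 NK cell gene (cytotoxic median 2.97, NK median 1.92). The T cell, cytotoxic and NK lists were still called there (fry adjusted p = 0.0102, 0.0102 and 0.0113).

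**Figure D2:**
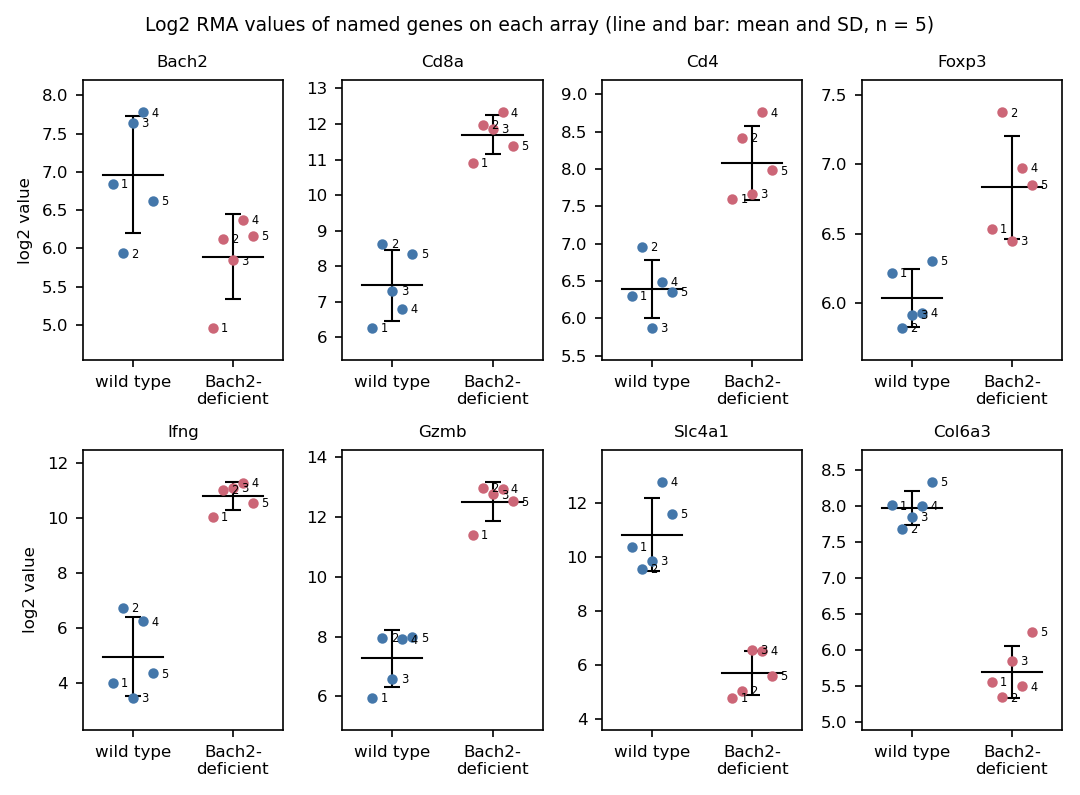
Log2 RMA values of 8 named genes on each array, wild type against Bach2-deficient; points are arrays numbered by replicate, lines and bars are mean and SD (n = 5), and axes do not start at 0. For Cd8a, Cd4, Foxp3, Ifng and Gzmb every Bach2-deficient array lies above every wild-type array, for Slc4a1 and Col6a3 every one lies below, and for Bach2 the groups overlap.

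Foxp3, the lineage factor of regulatory T cells, rose 1.74-fold, from 6.03 ± 0.21 to 6.84 ± 0.37 (log2, SD, n = 5 each; change 0.80, SE 0.18, 95% interval 0.40 to 1.20, limma adjusted p = 0.00877). The per-array difference Foxp3 minus Cd4 differed by -0.89, Bach2-deficient minus wild type (exact permutation p = 0.0317), and Foxp3 minus the T cell list mean by -2.05 (exact p = 0.00794). On the regulatory T cell list, 12 of 16 measured genes rose, also adjusted over the list alone, with a median of 1.51 (fry adjusted p = 0.00178; adjusted p = 0.168 with an estimated correlation). The costimulatory receptor genes Tnfrsf18 (GITR) and Tnfrsf4 (OX40) rose by 2.48 and 1.74; activated T cells of other kinds express them too. Ccr8 (0.66), Ikzf4 (0.43), Nrp1 (0.15) and Gpr83 (-0.21) did not pass. Of 10 inhibitory receptor genes, 8 rose (8 adjusted over the list alone), with a median of 1.98 (adjusted p = 0.000347; adjusted p = 0.128 with an estimated correlation). Among them were Tox, a transcription factor of chronically stimulated T cells (2.90), and Havcr2, encoding TIM-3 (2.47). Btla (1.22) and Cd200 (-0.08) did not pass. Of 12 naive and memory T cell genes, 8 rose and 2 fell, also adjusted over the list alone, with a median of 1.11 (adjusted p = 0.00588; adjusted p = 0.248 with an estimated correlation). The chromatin organiser Satb1 rose by 2.91 and the survival gene Bcl2 by 1.02, while Igfbp4 (-1.04) and Dapl1 (-0.67) fell. Averaged over its 5 probe sets, of which 4 pointed the same way, Bcl2 did not pass (0.44, adjusted p = 0.0619). With the melanocyte covariate Cd4 (1.12, adjusted p = 0.203) and Foxp3 (0.49, adjusted p = 0.409) did not pass, and the regulatory (median 1.26, adjusted p = 0.106) and the naive and memory lists (median 0.36, adjusted p = 0.319) were no longer called. The inhibitory receptor list was still called there (median 1.28, fry adjusted p = 0.0258). No single member of the 3 lists passed there, and with the Xist term 4 regulatory and 2 naive and memory genes rose and 0 of the latter fell. A single naive and memory gene fell without wild-type replicate 1, 2, 3 or 5 and without Bach2-deficient replicate 2, 4 or 5.

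Interferon-responsive and antigen-presentation genes rose with the lymphocyte genes. Of 22 genes on the interferon-γ list, 21 rose, with a median of 2.73 (fry adjusted p = 0.000108; adjusted p = 0.128 with an estimated correlation). Iigp1, an immunity-related GTPase, rose by 5.04 and the transcription factor gene Irf1 by 3.24; Socs1 changed by 0.37 and did not pass. Of 21 genes on the type I interferon list, 19 rose, with a median of 2.20 (adjusted p = 0.000168; adjusted p = 0.128 with an estimated correlation). The nucleic acid sensor gene Zbp1 rose by 3.61 and Dhx58 by 2.20, while Rsad2 (0.30) and Isg20 (-0.13) did not pass. Many genes of this list also respond to interferon-γ. All 18 antigen-presentation genes rose, with a median of 1.84 (adjusted p = 0.000115; adjusted p = 0.128 with an estimated correlation). The peptide transporter gene Tap1 rose by 3.04, although 2 of its 4 probe sets pointed the other way, and the immunoproteasome gene Psmb10 by 1.73. Adjusted over the list alone, 21, 19 and 18 members passed, and with the melanocyte covariate over all genes 7, 1 and 2. The list medians there were 2.14, 1.83 and 1.53, and the lists were still called (fry adjusted p = 0.0102, 0.0113 and 0.0102). The poly-A controls differed on the same arrays by -2.07.

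**Figure D3:**
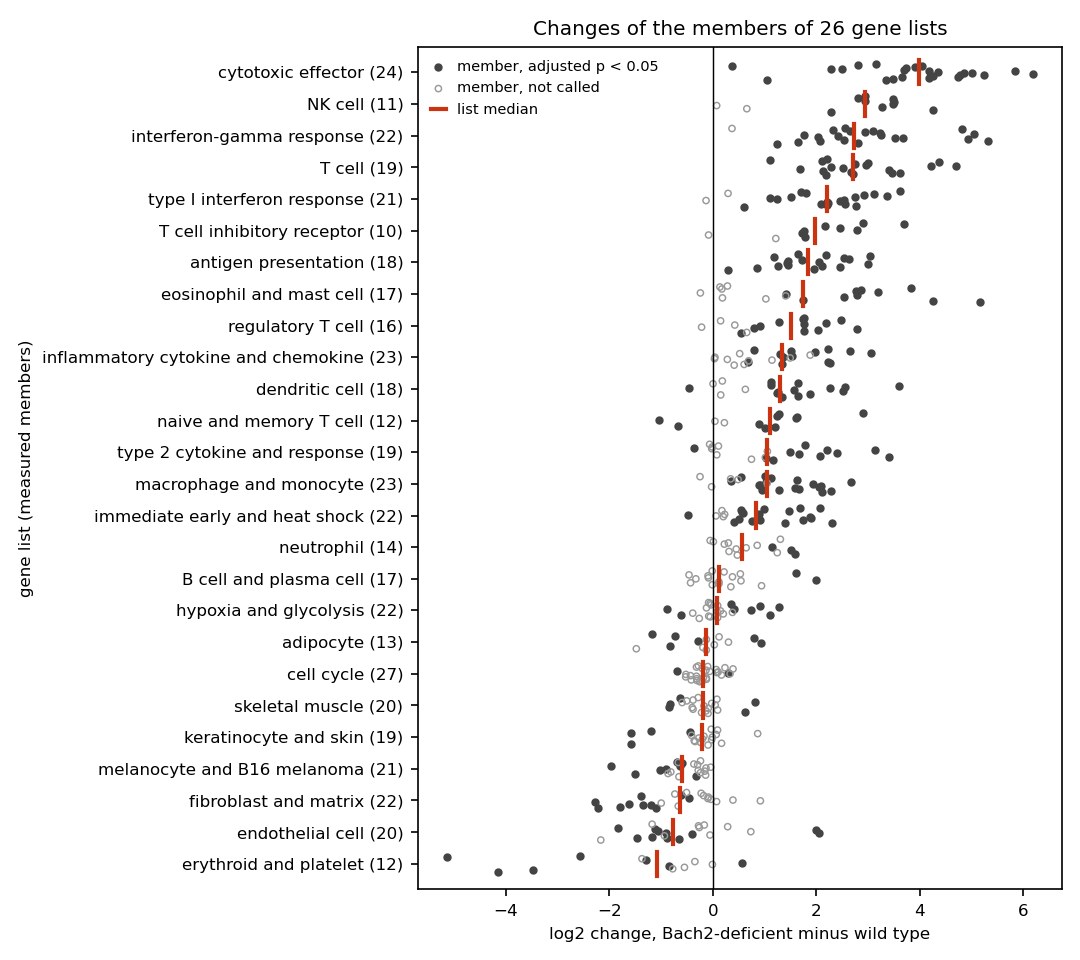
Log2 change of each measured member of the 26 tested gene lists, Bach2-deficient minus wild type; filled points passed a limma adjusted p of 0.05, open points did not, and red bars are list medians. Medians run from 3.98 for cytotoxic effector genes to -1.07 for erythroid and platelet genes.

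Among myeloid cells, 18 of 23 macrophage and monocyte genes rose, with a median of 1.05 (fry adjusted p = 0.00125; adjusted p = 0.168 with an estimated correlation). Cd300lf rose by 2.10 and the growth factor receptor gene Csf1r by 1.93. Of 18 dendritic cell genes, 13 rose, with a median of 1.30 (adjusted p = 0.000440; adjusted p = 0.128 with an estimated correlation). Naaa, a lysosomal amidase, rose by 3.60 and the costimulatory ligand gene Cd86 by 2.53, while Fscn1 fell (-0.46). Of 17 eosinophil and mast cell genes, 10 rose, with a median of 1.74 (adjusted p = 0.00493; adjusted p = 0.214 with an estimated correlation). They included Alox15 and Siglecf, a sialic acid receptor of eosinophils (3.83), and 6 members were in the dimmest 30% of genes. Gata2 (1.41), Cpa3 (1.03), Tpsb2 (0.29), Epx (0.19), Prg3 (0.18), Tpsab1 (0.14) and Mcpt4 (-0.24) did not pass. Of 19 type 2 cytokine and response genes, 10 rose, with a median of 1.06 (adjusted p = 0.000341; adjusted p = 0.128 with an estimated correlation). Gata3 rose by 2.39 and Chil3, a chitinase-like protein of macrophages, by 1.68. Il4 (3.13) and Il13 (1.49) were among those that rose, Il5 changed by -0.02 without passing, and Il9 fell (-0.37). The wild-type means of Alox15 (4.24) and Il13 (3.89) and both means of Il9 (3.55 and 3.18) lay under 4.98, so these sizes are not exact. Of 23 inflammatory cytokine and chemokine genes, 13 rose, with a median of 1.35 (adjusted p = 0.00588; adjusted p = 0.168 with an estimated correlation). Osm rose by 2.66 and Il18 by 1.54. Adjusted over the list alone, 19, 13, 11, 12 and 15 members of these 5 lists rose, and Fscn1 and Il9 fell. The neutrophil list did not pass, with a median of 0.56 (adjusted p = 0.0698; adjusted p = 0.348 with an estimated correlation). Of its 14 genes, Csf3r (1.60), Il1r2 (1.51) and Mmp8 (1.14) rose, the same 3 as adjusted over the list alone, while S100a8 (0.01) and S100a9 (-0.05) did not pass. The B cell and plasma cell list did not pass either, with a median of 0.12 (adjusted p = 0.536; adjusted p = 0.722 with an estimated correlation). Of its 17 genes, 2 rose, also adjusted over the list alone. These were Tnfrsf13b (1.60) and Ighm (2.00), whose _s_at probe set was 1 of 4 among 11 that pointed up. The mean of the Ighm probe sets did not pass (0.16, adjusted p = 0.571). With the melanocyte covariate the macrophage (median 0.96, adjusted p = 0.0839), eosinophil and mast cell (median 0.63, adjusted p = 0.264) and inflammatory lists (median 1.01, adjusted p = 0.181) were no longer called. With the Xist term the inflammatory list was not called either (median 0.89, adjusted p = 0.223). The dendritic cell (median 0.94, fry adjusted p = 0.0356) and type 2 lists (median 1.04, fry adjusted p = 0.0266) were still called with the covariate. No single gene of the 7 lists passed with the covariate. With the Xist term 10 eosinophil and mast cell, 9 dendritic cell, 9 macrophage, 5 type 2, 1 inflammatory, 0 neutrophil and 0 B cell genes rose. With the dim-gene filter the eosinophil and type 2 medians were 2.79 and 1.73. The adjusted p of the neutrophil list ran from 0.0424 to 0.759 over the fry alternatives. It passed without Bach2-deficient replicate 1 (0.0457), 2 (0.0471) or 3 (0.0424) but not without replicate 4 (median 0.33, 0.196) or with the Xist term (0.759). The B cell median moved from -0.13 without Bach2-deficient replicate 4 to 0.45 without replicate 1, and it was -0.92 with the covariate, 0.52 with the Xist term and 0.56 with array weights.

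Genes of the tumor and its stroma moved the other way. On the melanocyte and B16 list, 8 of 21 genes fell, 13 adjusted over the list alone, with a median of -0.59 (fry adjusted p = 0.00903; adjusted p = 0.303 with an estimated correlation). The count of falls was 14 without Bach2-deficient replicate 1, 5 without replicate 2 or 4, 13 with array weights and 3 with the Xist term. S100b fell by 1.96 and Oca2, a pigmentation gene, by 0.90. Of 22 fibroblast and matrix genes, 10 fell, 12 adjusted over the list alone, with a median of -0.64 (adjusted p = 0.000816; adjusted p = 0.168 with an estimated correlation). Col6a3, a collagen VI chain, fell by 2.28 and Acta2, smooth muscle actin, by 2.22 (an _s_at probe set). Of 20 endothelial genes, 9 fell and 2 rose, 10 and 3 adjusted over the list alone, with a median of -0.78 (adjusted p = 0.000173; adjusted p = 0.128 with an estimated correlation). Ptprb, a phosphatase of vascular endothelium, fell by 1.82 and Egfl7 by 1.18 (an _x_at probe set). Pecam1 (2.00), which leukocytes also express, and Flt1 (2.06) rose. Of 19 keratinocyte and skin genes, 4 fell, also adjusted over the list alone, with a median of -0.20 (adjusted p = 0.00230; adjusted p = 0.128 with an estimated correlation; adjusted p = 0.0593 with camera's preset correlation). These were Perp (-1.58), Sbsn (-1.20, an _x_at probe set), Dsc3 (-1.58) and Pkp1 (-0.43), and 11 members of the list were among the dimmest 30% of genes. The adipocyte list moved down (median -0.12, adjusted p = 0.000835; adjusted p = 0.348 with an estimated correlation; adjusted p = 0.276 with the preset correlation). Of its 13 genes, Fabp4 (-0.82), Scd1 (-0.73), Thrsp (-1.17) and Pck1 (-0.28) fell, and Lipe (0.94) and Pparg (0.80) rose; adjusted over the list alone 5 fell and 2 rose. Falls numbered 2 without wild-type replicate 3 or Bach2-deficient replicate 5, and rises 1 without Bach2-deficient replicate 2 or 4. With the mean of probe sets 1 rose and 2 fell. The median was -0.73 with the dim-gene filter and -0.03 after repeated quantile normalization. Over all genes tested the median change was -0.064 in the main fit and 0.0086 with that filter. The mean of the Scd1 probe sets did not pass (-0.50, adjusted p = 0.0672). The skeletal muscle list did not pass (median -0.19, adjusted p = 0.0636; adjusted p = 0.438 with an estimated correlation). Of its 20 genes, 12 of them among the dimmest 30%, Myh1 (-0.84, an _x_at probe set), Tnnt3 (-0.63) and Myh8 (-0.83) fell while Neb (0.81) and Atp2a1 (0.63) rose, the same counts as adjusted over the list alone. In both groups the means of Pkp1, Pck1, Myh1 and Neb lay under 4.98, as did the wild-type mean of Lipe (4.40) and the Bach2-deficient means of Tnnt3 (4.55) and Myh8 (4.65), so the sizes of their changes are not exact. The fry test of the skeletal muscle list passed without wild-type replicate 4 (adjusted p = 0.0113) and without Bach2-deficient replicate 3 (adjusted p = 0.0487), with the mean of probe sets (adjusted p = 0.0186) and with array weights (adjusted p = 0.0299). The unstandardized fry test (adjusted p = 0.0449) and the exact test of list means (adjusted p = 0.0359) passed as well, and over the fry alternatives its adjusted p ran up to 0.310 (Xist term). Its median was -0.13 without wild-type replicate 1 and -0.10 after repeated quantile normalization, where the keratinocyte median was -0.11. With the Xist term the endothelial median was -0.42 with 3 falls, 1 adipocyte gene rose and 1 fell (median -0.24), 0 keratinocyte genes fell, and 1 muscle gene rose and 0 fell. With the melanocyte covariate, 2 fibroblast genes fell and no gene of the endothelial, skin, fat and muscle lists passed. By fry, lists still called there were fibroblast (median -0.91, adjusted p = 0.0236), endothelial (-0.66, 0.0107), keratinocyte (-0.27, 0.0102) and adipocyte (-0.08, 0.0369). The muscle list was not called there (-0.22, 0.266). On these arrays the T cell list median differed by 2.71 and the poly-A controls by -2.07.

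The cell cycle list gave no directional call (median -0.18, fry adjusted p = 0.460; adjusted p = 0.761 with an estimated correlation). Of its 27 genes, the replication helicase gene Mcm4 rose (0.30, adjusted p = 0.0478, an _x_at probe set) and the proliferation marker gene Mki67 fell (-0.69, adjusted p = 0.0192); adjusted over the list alone 0 passed. At an unadjusted p under 0.05, 7482 genes of all 18193 passed. The call of Mcm4 was lost in 8 of 10 fits that left out 1 array, and that of Mki67 without Bach2-deficient replicate 2 (adjusted p = 0.0530). Without Bach2-deficient replicate 1 the cell cycle list passed as lower (median -0.30, adjusted p = 0.00931), and with the melanocyte covariate it passed as higher (median 0.41, adjusted p = 0.0193). Its adjusted p ran up to 0.694, without Bach2-deficient replicate 2 (median -0.08). Of its genes 10 fell without Bach2-deficient replicate 1 and 6 with array weights, and the median was -0.27 without wild-type replicate 3 and -0.43 with the Xist term, where none passed. The erythroid and platelet list fell (median -1.07, adjusted p = 0.00125; adjusted p = 0.128 with an estimated correlation). Its mean per array was 8.38 and 7.85 on wild-type replicates 4 and 5 and 6.79 to 6.93 on wild-type replicates 1 to 3. The Bach2-deficient arrays read 5.41 to 6.07, so part of the size of the fall comes from those 2 wild-type arrays. Of its 12 genes, 6 fell and 1, the integrin gene Itga2b (0.57), rose; adjusted over the list alone 7 fell and 1 rose. Hba-a1, an α-globin gene, read 3.32 in both groups, near the lowest values of the table. With the melanocyte covariate the list was no longer called (median -0.67, adjusted p = 0.0790) and 0 members fell; with the Xist term 2 did. Itga2b did not pass without wild-type replicate 2 or 3 or without Bach2-deficient replicate 2 or 5. The hypoxia and glycolysis list did not pass (median 0.09, adjusted p = 0.0942; adjusted p = 0.550 with an estimated correlation). Of its 22 genes 6 rose, among them the glycolytic regulators Pfkfb3 (1.29) and Pfkfb4 (0.92), and 2 fell, P4ha2 (-0.88) and Car9 (-0.62); adjusted over the list alone 7 rose and 3 fell. It passed without Bach2-deficient replicate 4 (adjusted p = 0.0459), with the melanocyte covariate (0.0233), by unstandardized fry (0.0257) and by the exact test of list means (0.0281). Over the fry alternatives its adjusted p ran up to 0.517, with the mean of probe sets (median 0.01, 5 rose and 4 fell). Its median was also 0.01 without Bach2-deficient replicate 1 (0.298) and with array weights, 0.02 with the Xist term (1 rose and 0 fell) and 0.03 after repeated quantile normalization. It was 0.04 to 0.06 without Bach2-deficient replicate 3 or wild-type replicate 2 or 4, and 0.19 with the covariate, where no member passed. Falls numbered 4 without Bach2-deficient replicate 1, 2 without wild-type replicate 2 and 1 without any other array. Of 22 immediate early and heat shock genes, 17 rose, 18 adjusted over the list alone, with a median of 0.83 (adjusted p = 0.000341; adjusted p = 0.128 with an estimated correlation). Junb rose by 1.47 and Atf3 by 1.39, and Hspe1 fell (-0.48). With the Xist term 2 of these genes rose (median 0.72), and with the melanocyte covariate none passed (median 0.52). The list was still called in both (fry adjusted p = 0.0167 and 0.0266). Such genes respond to tissue dissociation as well as to signals within a tumor. The 3′ minus 5′ difference of Actb, a sign of RNA integrity, was 0.745 ± 0.195 in Bach2-deficient and 1.00 ± 0.152 in wild-type arrays (SD, n = 5 each; exact permutation p = 0.0556), and that of Gapdh was 0.591 in both (exact p = 1). The Actb difference passed without wild-type replicate 4 (exact p = 0.0397) and without Bach2-deficient replicate 1 (exact p = 0.0159).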

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

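The tests of host sex, of Foxp3 and of the erythroid genes below were chosen only after the result was seen; those of other splits and of a shift by expression level were chosen before.

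The rise of T cell, cytotoxic effector and interferon-γ genes is the pattern to follow up first, because the poly-A controls separated the genotypes without overlap. The labels give no batch, and whether spike amount, RNA input or labelling batch set these controls apart was not tested. A shift by expression level left in the normalized values is argued against for these 3 lists. Quantile normalization takes out most such shifts beforehand, so the test does not bear on other effects of a labelling batch. The medians of the 3 lists lay at percentile 100 of 10000 random lists matched on mean expression, whose highest medians were 1.22, 0.84 and 0.69 against 2.71, 3.98 and 2.73. Any other handling difference that followed genotype, such as tumor dissection, cannot be told apart from it. Host sex stays open as well: with an Xist term the T cell list still changed by a median of 3.05 (fry adjusted p = 0.00294), but that rests on 1 array, the Xist-high Bach2-deficient replicate 2. Its T cell list mean was 10.01, against 7.23 at most in wild type and 8.92 to 10.3 on the other Bach2-deficient arrays. A larger infiltrate of activated lymphocytes in Bach2-deficient tumors may account for the pattern and was not separated from handling by any test.

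The measured rise of Foxp3 was smaller than that of Cd4 and of the T cell list. Compression of dim values by array background stays open. The 21 T cell and cytotoxic genes no brighter in wild type than Foxp3 plus 0.5 rose by a median of 3.67, above the upper limit of 1.20 for Foxp3. That excludes nothing, because probe sets differ in affinity and background, so their levels cannot be matched. A smaller share of regulatory cells among CD4 T cells is a candidate explanation and also stays open. The difference of Foxp3 minus Cd4 is the pattern itself and tests no explanation of it; it was -0.893 (exact permutation p = 0.0317; -1.09 to -0.76 with each array left out, exact p at most 0.0397). Foxp3 minus Cd3e differed by -1.32 (exact p = 0.00794). Handling and sex stay open, less Foxp3 RNA per regulatory cell was not tested, and no cells were counted.

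Erythroid genes had a lower median than the tumor and stromal lists. Dilution of all other cells by leukocytes stays open. The 7 erythroid members had a median change of -2.57 (upper quartile -1.07), and the lowest median of the melanocyte, fibroblast and endothelial lists was -0.78. The basement membrane family, chosen after the data were seen, had a median of -1.21, which that upper quartile does not lie below. Of the 7 members, 4 fell, and Hba-a1 lies too near the floor to bear on it. The mean of the erythroid and platelet list also varied within wild type, from 6.79 to 8.38. Different handling of blood, such as bleeding or red cell lysis, remains possible: of the array sets that the poly-A controls divide, 0 held both groups, so handling and genotype cannot be told apart. Less blood in Bach2-deficient tumors may equally account for it and was not tested.

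Other splits of the arrays were refitted to ask whether a random division of the samples gives as many calls. Of 100 splits, the real one included, 1 gave 5226 genes, the real one, and 1 gave 21 lists; the highest of the others gave 2266 genes and 14 lists. A random division of these arrays thus rarely gives as many calls, within the limit of 100 splits. Every other split mixed the genotypes, and the test cannot tell genotype from sex or handling that followed it. The split with 2266 genes exchanged wild-type replicate 4 with Bach2-deficient replicate 1, so it kept most of the real division.

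A single array stood apart from the other 4 of its group in 18 of 226 sets of values tested. Chance gives about 1 in 20 for independent sets, but these sets share genes that vary together. An odd array is thus counted many times, and no excess over chance is shown. Bach2-deficient replicate 1 was low for Gbp2b (7.0), Cxcl9 (11), Gzmb (11.4), Iigp1 (10.92), Zbp1 (11.05), Tnfrsf18 (9.242) and Csf1r (11.62). It was also low for the list means of interferon-γ (10.01), antigen presentation (11.52) and macrophage genes (10.57), and high for S100b (9.386). Bach2-deficient replicate 2 was high for Xist (11.86) and low for the Y-linked genes Eif2s3y (4.504), Kdm5d (2.897) and Uty (3.273). Bach2-deficient replicate 3 was high for Il1r2 (11.36), and wild-type replicate 1 was low for Zbp1 (6.791) and Atf3 (9.484). Among 9160 probe sets with no gene symbol here, which the comparisons did not use, 368 were higher and 302 lower in Bach2-deficient tumors (limma, adjusted p under 0.05 over these probe sets).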

How the results depend on the processing

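The Xist term was added after the data were seen; the other alternatives here were fixed before. The numbers of changed genes stayed within 1.5 times of 5226 under the dim-gene filter (5043), mean of probe sets (5188), median centring (5150), repeated quantile normalization (5174), trended robust moderation (5275), array weights (6704) and single probe sets (6075), and called lists numbered 21 or 22 where tested. A minimum change of 1 left 2139 genes (1469 rose, 670 fell) by construction. With the melanocyte list mean as covariate 98 genes passed (64 rose, 34 fell) and 16 lists; the covariate differed between genotypes, so it takes up much of the contrast. The melanocyte list median of 0.0945 there follows from the covariate, which is the mean of that list. The B cell (-0.917, not called) and cell cycle (0.408, called as higher, fry adjusted p = 0.0193) medians reversed, for a cause not tested. With the Xist term 1417 genes passed (1030 rose, 387 fell; 72.7% of calls rose, against 56.7%) and 20 lists, with 1 array of 5 left to separate sex from genotype. Named genes that lost their call there were Csf3r, Epb42, Fabp4, Ighm, Il1r2, Mcm4, Mki67, Myh1, Osm, Perp, Pfkfb3, Sbsn, Tnfrsf13b and Tnnt3. Their changes with the term were 0.677 to 1.45 times those without it, 7 smaller and 7 larger (Epb42 -3.33, Ighm 2.02, Tnfrsf13b 2.19). camera called 20 lists with a preset correlation (without keratinocyte and adipocyte, with neutrophil at an adjusted p of 0.0143) and 0 with an estimated one. The exact test of list means and unstandardized fry called 23 lists each, adding skeletal muscle and hypoxia.

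With each array left out, changed genes ranged from 3658 to 5925, rises from 2270 to 3120, falls from 1388 (without Bach2-deficient replicate 2; 1447 without replicate 4) to 2807, and lists from 21 to 23. Bach2 probe sets ranged from -1.24 to -0.84 (1436515_at), -0.47 to -0.16 (1437667_a_at) and -1.33 to -0.84 (1445460_at), poly-A controls from -2.12 to -2.02, Actb 3′ minus 5′ from -0.338 to -0.217 and Gapdh from -0.0121 to 0.0130. The Gapdh value, near 0, reversed to -0.0103 and -0.0121 without wild-type replicates 1 and 4 and to -0.00766 and -0.00469 without Bach2-deficient replicates 4 and 5. The B cell list median ranged from -0.127 (without Bach2-deficient replicate 4, a reversal) to 0.449; the cause was not tested. Of the named genes, 9 leave-one-out values lost their call, all of Mcm4 or Mki67.

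The groups share replicate numbers. Same-numbered arrays deviated together with correlations of 0.32, 0.01, 0.22, 0.09 and 0.06, and only numbers 1 and 3 matched best with themselves. No chance range was computed for these values, so whether the numbers pair any tumors is not known. With the replicate block 4952 genes passed (2842 rose, 2110 fell) and 21 lists, and of named genes and lists only the call of Mcm4 changed (limma adjusted p = 0.0740). Signal over background limits the dim genes, and no detection calls were used.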

Other observations

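The families in the next paragraph were chosen after the data were seen; the test of the Bach2 neighbours was chosen before.

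Genes of contractile and perivascular cells and of the basement membrane fell, and no list above holds most of them. Of 16 contractile and pericyte genes, 11 fell and 0 rose by limma (11 fell, and 1, Cnn2 at 0.32, rose adjusted over the list alone), with a median of -0.57. At an unadjusted p under 0.05, 7482 genes of all 18193 passed. Tagln, an actin-binding protein of smooth muscle, fell by 2.20, the myosin light chain gene Myl9 by 1.97 and the pericyte marker gene Rgs5 by 2.53, to a mean of 4.53, which is among the dimmest 30% of levels, so that size is not exact. Of 13 basement membrane genes, 9 fell (10 adjusted over the list alone), with a median of -1.21, which was -0.69 with the mean of all probe sets of a gene, -0.90 with the melanocyte covariate and -1.40 with the Xist term. The contractile median was -0.68 with the dim-gene filter and -0.39 with that covariate. Col4a1 and Col4a2, the main collagen IV chains, fell by 2.39 and 1.87, the laminin gene Lama4 by 1.57 and the nidogen gene Nid1 by 1.78. On the rising side, all 8 GIMAP genes, GTPases of lymphocytes, rose (all 8 adjusted over the list alone), with a median of 2.40 and a top value of 3.77 for Gimap7. Of 7 Schlafen genes, 5 rose (6 adjusted over the list alone), with a median of 1.80; Slfn5 rose by 3.18 and Slfn8 by 2.91, while Slfn9 (0.34) and Slfn3 (-0.10) did not pass. With the melanocyte covariate the medians of these families were 1.63 and 1.17. The arrays differed in the poly-A controls by -2.07.

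A targeted allele made in another strain could carry flanking DNA of that strain and so shift genes beside Bach2. The 40 nearest measured genes, 20 on each side in the gene order of GRCm38.p6, were tested against 10000 random stretches of as many neighbouring genes. Their median absolute moderated t of 1.93 lay at percentile 63.2, and 8 of the 40 (20%) were called, against 28.7% of all genes. The neighbours as a set thus did not stand out from other stretches. With 28.7% of all genes called, a median over 40 genes cannot show effects on a few of them, so such effects are not excluded.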
